A study of Rattus norvegicus with 14 samples.

How the data were processed

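Small intestine of rats aged 20 days had been perfused with HG or HF for 4 h or 20 min, and pairs of RNAs were hybridised to 2-colour arrays, per the labels. The primer array carried the primers of a 3DNA labelling kit, and the labelling of the other arrays is not given in the sources used here. The authors deposited 1 table of log ratios, treated here as log2 values, with 4952 probes, 14 arrays and 0 missing values. Per the labels, channel 1 holds the HG and channel 2 the HF sample on every array at 4 h and 20 min, but the dye of each channel is given for the primer array alone. The scanner, background correction, normalization, base of the logarithm and direction of the ratio are not given in the sources used here. The medians of the 14 columns lie between -0.07 and 0.02, so the values look centred already, by a method that stays unknown, as do the scale and the direction. Base 2 is an assumption. With another base every difference would change by the same factor and every fold would be raised to the same power. Signs, p-values and counts of calls would not change.

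Probe names came from the platform annotation. Of the 4952 probes 4426 have 1 gene symbol, 2 have several and 524 have none. The reference gene table of the GRCr8 assembly holds the Entrez identifier of 4371 of the 4426, and 0 symbols had to be changed. Each array was centred on its median, probes of 1 symbol were averaged (191 genes have several), and probes with several symbols or none were kept as features of their own, which left 4682 features, 4156 with a symbol. Signal intensities and background were not analysed here, so dim probes could not be set apart.

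Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes). A single fit of 12 replicates had 3 groups, 5 arrays at 4 h, 4 at 20 min and 3 self-self arrays, with 9 residual and 2.84 prior degrees of freedom. The comparisons were 4 h minus self-self, 20 min minus self-self, and 4 h minus 20 min. The self-self arrays served as the control because they carry the dye effect of each probe: the arrays 3HG and 3HF correlated with the HG and HF arrays at a median Pearson r of 0.44 across probes (Spearman 0.30). For the array 1HG, which holds extreme values, these were 0.09 and 0.25. A feature was called at a Benjamini-Hochberg adjusted p below 0.05. Gene lists with at least 3 measured members, 31 in all, were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Lists, comparisons, groups and the rule for named genes were fixed before the data were examined.

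Array 6 is a second array of pair 2. The design asked that it be averaged with array 2, with its sign turned below r = -0.3 and kept above r = 0.3 against the mean of arrays 1, 3, 4 and 5, and that it be left out in between. On the values as deposited r was 0.41 across features (Spearman 0.26), which taken literally keeps the sign. Array 6 also correlated with the self-self arrays 3HG and 3HF (Pearson r with array 6 of 0.36 and 0.55, Spearman 0.30 and 0.44) and 1HG (0.08 and 0.25). Its median Pearson r was 0.46 with the 20 min arrays and 0.34 with arrays 1 to 5, an order that swapped dyes and a shared array set would both give. With the median of the self-self arrays subtracted, r against the mean of arrays 1, 3, 4 and 5 was 0.04 (Spearman 0.06). Array 6 was left out on that second reading. This departs from the letter of the design and was decided after the values had been seen. The reading to the letter and 3 other treatments of array 6 were run as alternatives.

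The named genes are, per comparison, up to 10 called genes per direction with the largest difference and with groups that do not overlap, filled to 5 by the smallest p. A fixed set was added: Slc2a5, Slc2a2, Slc5a1, Khk, Fbp1, G6pc1, Slc34a2 and Si, which were measured, and Lct and Fos, not measured under those symbols. Another member of the set is not reported here. Up to 4 members with the smallest p were named for each list described.

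The steps were tested on simulated data, with normal noise drawn independently for each feature and 100 of the 4682 features changed by each size at once. So many changes make the adjusted p easier to pass: 191 features were called in the simulated 4 h test, and 3 in the data. The shares recovered hold for that setting and may be lower in the data. The 4 h test recovered 85% of changes of 1 and 96% of changes of 2 on the log2 scale with 10 false calls, and the 20 min test recovered 83% and 97% with 13 false calls. For 4 h against 20 min, with the changes put in at 4 h, these were 84% and 98% with 4 false calls, and with the changes put in at 20 min 92% and 97% with 8 false calls. In a simulation of the 4 h comparison camera found 3 of 3 lists of 20 genes shifted by 0.3 and 0 of the others, and smaller shifts were not simulated. The simulated genes were independent of each other, so false calls that arise from correlation between genes were not examined. With the correlation estimated from the data, 0 lists passed at 4 h.

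Alternatives covered the test against 0, centring, scaling to 1 median absolute deviation, quantile normalization, probes tested singly, array 6, the groups in the fit, robust empirical Bayes, array weights, the threshold, the replicate number as a block and each replicate left out. Chosen after seeing the data were 3 more: values of the self-self array 1HG beyond 2 set to missing, that array left out of the third comparison, and array 6 turned and averaged with array 2 with a dye term of 0 for that replicate. The primer array entered no test. Figures were drawn with matplotlib 3.10.9.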

Results

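RNA of small intestine from rats aged 20 days was compared on 14 arrays of 2 colours, each of which gives, for 4952 probes, the ratio of the RNAs in its 2 channels. The intestine had been perfused with solutions labelled HG and HF, and arrays that set HG against HF numbered 6 at 4 h and 4 at 20 min. The labels do not spell these names out. They are taken here to stand for high glucose and high fructose, from knowledge of the study rather than from its labels. On that reading the comparison asks which genes differ between intestine perfused with fructose and with glucose. No array is labelled as intestine without HG and HF, so a ratio cannot tell a rise with HF from a fall with HG. Each array at 4 h or 20 min set an HG sample against the HF sample of the same number, so a ratio is already a comparison of HG with HF. The 6 arrays at 4 h came from 5 pairs, since array 6 repeats pair 2. Another 3 arrays carried the same RNA in both channels (1HG, 3HG and 3HF, called self-self here), and 1 array carried the primers of the labelling kit with no tissue RNA named. The self-self RNA is also of 4 h perfusion, so the control for the arrays at 20 min is RNA of 4 h. Its names are those used in pairs 1 and 3 at 4 h. Nothing in the labels says whether the pairs came from different animals, so the p-values measure the spread between these arrays.

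The spread of the ratios differed between arrays. Their SD over all probes lay between 0.33 and 0.40 on arrays 1 to 5 and on the 4 arrays at 20 min, and was 0.18 on the primer array. Array 6 had an SD of 0.82. The self-self array 1HG had an SD of 1.39 and 227 probes beyond 2, of which 147 were among the first 750 probe numbers and 79 among those above 4500. The number of arrays limits the precision of every value below.

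The direction of a ratio is not stated in the sources used here. A positive ratio is likely to mean more RNA with HF, and is called the HF side below, with HG side for the opposite. The basis is that the title of array 6 marks its HG sample with a 5 and its HF sample with a 3, read as the dyes Cy5 and Cy3, and that genes called below changed sign on it relative to the self-self arrays: 3 of 3 called at 4 h, and 18 of the 21 features called between the times that lay further from the self-self arrays at 4 h than at 20 min, against 46.6% of all features. The 7 that lay further from the self-self median at 20 min, with both genes called at 20 min among them, are set apart, a sort made after the values had been seen. Their ratios did not all arise at 20 min. From the self-self mean Akr7a3 differed by 0.36 at 4 h and -0.39 at 20 min, and Rnf4 by 0.38 and -0.28. Of the 7 features 5 changed sign relative to arrays 1 to 5, so sign change was common there too, and Barhl1 and Hspbp1 had the same sign on array 6 as at 20 min. Not every large ratio did so, since Kcnv1 and Tgfb2 had means of -1.21 and -1.05 on arrays 1 to 5 and ratios of -1.39 and -1.23 on array 6. Slc2a5, which encodes GLUT5, the transporter that takes up fructose and is known to be induced by it, had a mean of 1.65 ± 0.25 (SD, n = 5) on arrays 1 to 5 and -1.66 on array 6. The labels put HG in channel 1 and HF in channel 2 on array 6, as on the other arrays at 4 h and 20 min. They do not give the dye of each channel there, so the swap of dyes stays an inference. Array 6 was left out of the tests, a choice made after the values had been seen. The plan written before had been to average it with array 2 as deposited if it correlated above 0.3 with the mean of arrays 1, 3, 4 and 5. It did (Pearson r = 0.41 across genes), but r was 0.04 once the median of the self-self arrays had been subtracted. Averaging it in as deposited gave 0 called genes in each of the 3 comparisons. Every count of calls below therefore depends on this choice.

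**Figure D1:**
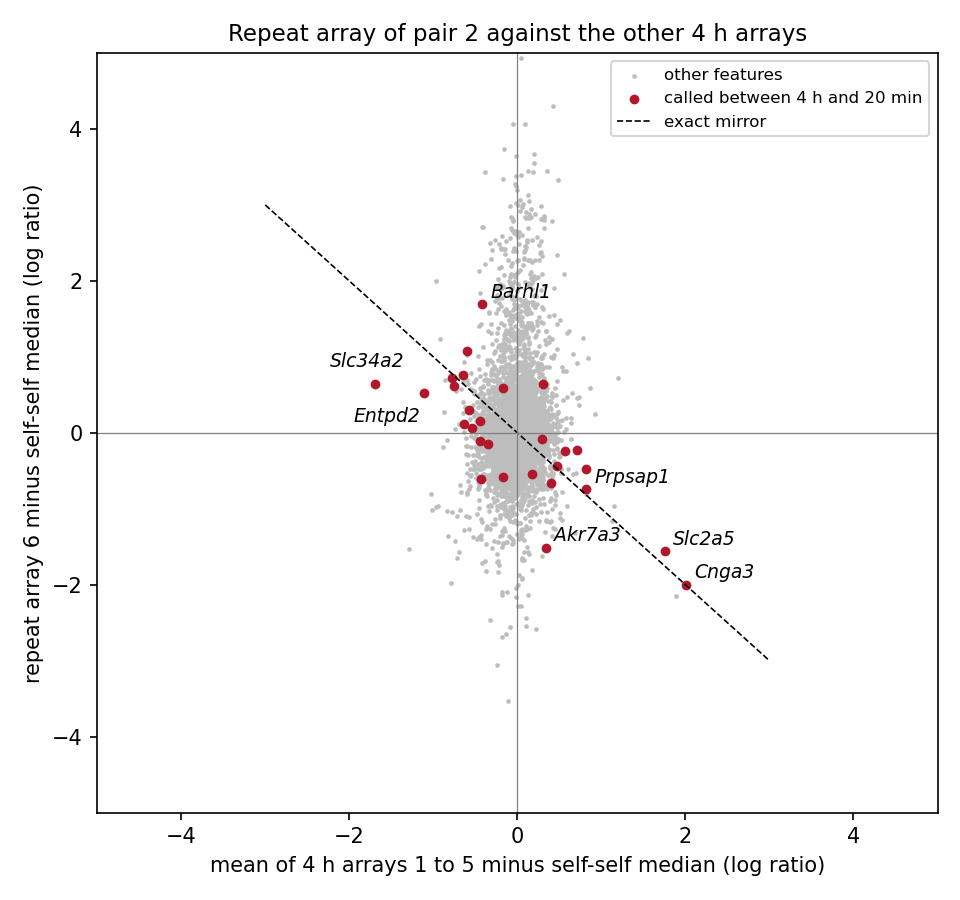
Ratio on repeat array 6 (vertical axis) against the mean ratio of the 4 h arrays 1 to 5 (horizontal axis), both as log ratios minus the median of the 3 self-self arrays. Each point is 1 of 4682 features (1 lies outside the range drawn), red points are the 28 features called between 4 h and 20 min, and the dashed line is an exact change of sign; Cnga3 and Slc2a5 lie near it, at array 6 ratios of -2.12 and -1.66 before subtraction.

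The first comparison asked which genes differed between HF and HG intestine after 4 h, relative to the self-self arrays. The gene for the fructose transporter GLUT5, Slc2a5, was higher on the HF side by 1.69 ± 0.16 on the log2 scale (SE; 3.23-fold; limma adjusted p = 0.000397), with 5 arrays at 4 h between 1.33 and 1.95 and self-self arrays at -0.04 ± 0.17 (SD, n = 3). Its direction is no separate finding, since Slc2a5 helped to set which side is called HF. Cnga3, known as a subunit of the cyclic nucleotide-gated channel of cone photoreceptors, was higher by 2.04 ± 0.12 (SE; 4.12-fold; adjusted p = 6.58e-06), with 5 arrays between 1.55 and 2.11. Entpd2, an ectoenzyme that splits extracellular nucleotides, was lower on the HF side by -1.15 ± 0.17 (SE; adjusted p = 0.0408), with a mean of -1.06 ± 0.34 (SD, n = 5) at 4 h. Entpd2 passed in only 10 of 23 alternatives and in 2 of 8 with 1 array left out. Of 4682 features tested these 3 passed, 2 on the HF side and 1 on the HG side, and 467 had an unadjusted p below 0.05. In all 3 the arrays of the 2 groups did not overlap, which held for 6.71% of all features against 3.57% by chance. Quantile normalization between arrays raised the differences of Cnga3 and Slc2a5 to 3.28 and 2.74.

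Large ratios that did not pass the test included further genes of sugar and phosphate handling. G6pc1, the catalytic subunit of the glucose phosphatase that releases free glucose, differed by 1.83 ± 0.49 (SE; adjusted p = 0.244). Fbp1, the fructose bisphosphatase of gluconeogenesis, differed by 1.15 ± 0.24 (adjusted p = 0.164). Slc34a2, the sodium phosphate cotransporter of the brush border, had the largest negative difference of the genes named here, -1.71 ± 0.34 (adjusted p = 0.131), with 5 arrays between -2.49 and -0.74. Prpsap1 (0.89), Nat1 (0.71) and Ldhb (0.64) had the next smallest p on the HF side, all with an adjusted p of 0.128. On the HG side these were Cyp51, a demethylase of sterol synthesis (-0.68; adjusted p = 0.128), and Apoa1 (-0.59) and Emp1 (-0.68), both with an adjusted p of 0.155. The sugar genes Khk, which encodes ketohexokinase, and Si, which encodes sucrase-isomaltase, had differences of 0.06 ± 0.10 and 0.24 ± 0.26 (SE; adjusted p = 0.86 and 0.785), which were 0.01 and 0.02 without 4 h replicate 1. For Slc2a2 (GLUT2) and Slc5a1 (SGLT1) the differences were -0.12 ± 0.17 (from -0.21 to -0.05 with 1 array left out) and -0.04 ± 0.25, and both changed sign when the arrays were scaled to 1 spread.

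**Figure D2:**
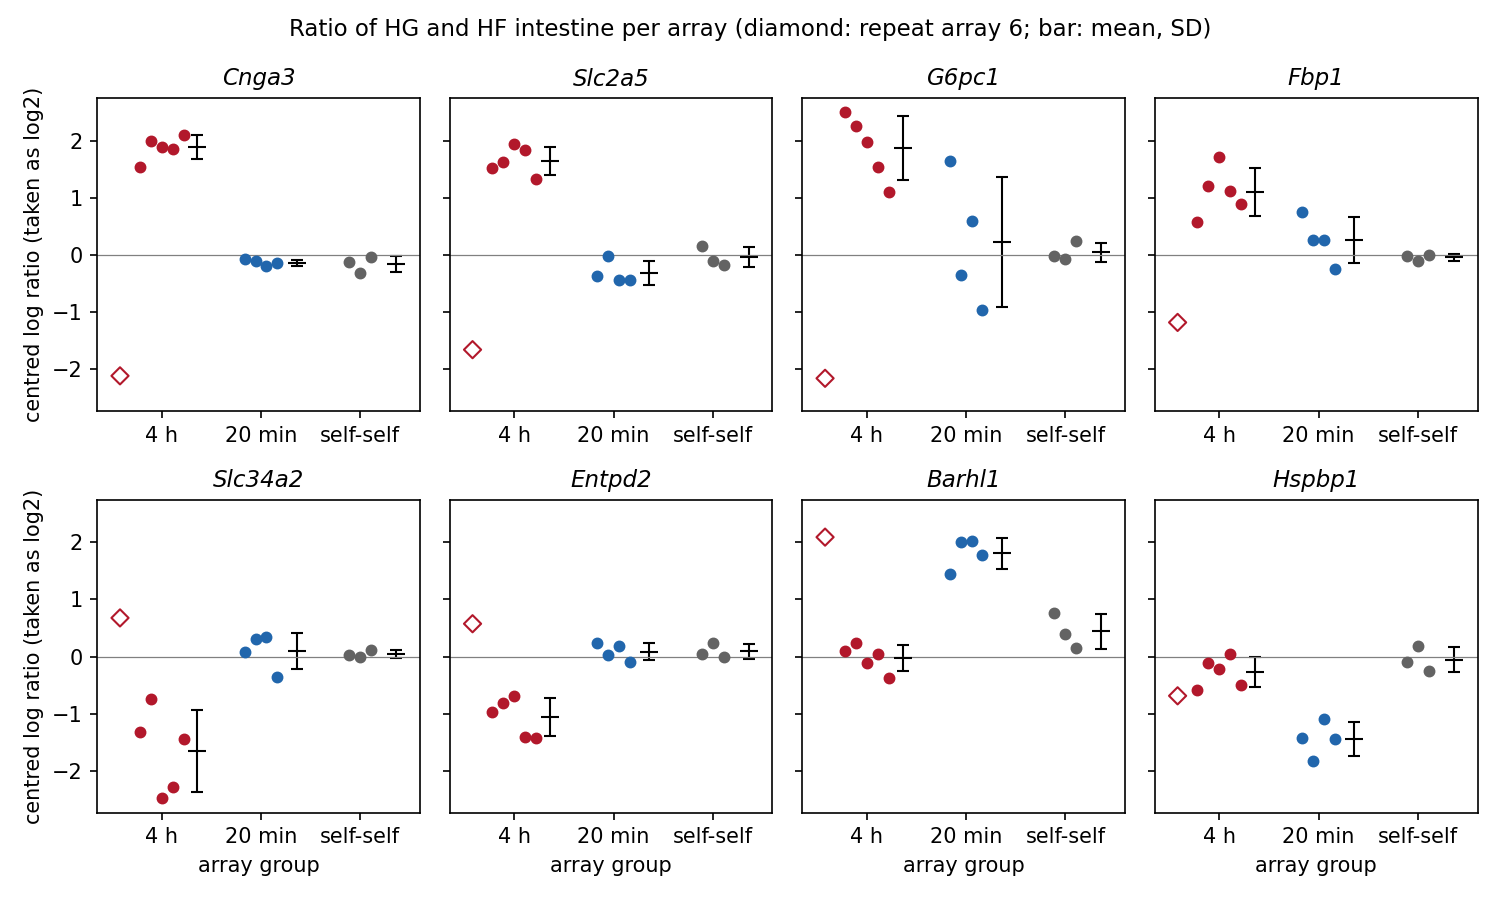
Centred log ratio (taken as log2, vertical axis) of 8 genes on each array, by array group. Dots are the 5 arrays at 4 h, 4 at 20 min and 3 self-self arrays, black bars give each group's mean with 1 SD, and the open diamond is repeat array 6; Slc2a5 averages 1.65 at 4 h, -0.32 at 20 min and -0.04 on the self-self arrays, while Barhl1 averages 1.81 at 20 min and -0.02 at 4 h.

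Of 31 gene lists fixed beforehand, 21 of pathways and 10 of cell type markers, 4 differed at 4 h in limma's camera test and 0 with an estimated correlation. Gluconeogenesis genes were higher on the HF side as a group (11 measured, 8 of them above 0, median 0.27; adjusted p = 0.00334, and 0.105 with an estimated correlation). None of the 11 passed over all genes, and 5 passed when adjusted over the list alone, among them G6pc1, Fbp1, Slc37a4 (0.55), the glucose phosphate transporter that works with G6pc1, and Gpt (0.36), an alanine aminotransferase. Glycolysis genes were also higher (28 measured, 20 above 0, median 0.15; adjusted p = 0.00585, and 0.105 with an estimated correlation). None passed over all genes and 2 did when adjusted over the list alone, Ldhb (0.64), a lactate dehydrogenase, and Pfkfb2 (0.59), which sets the level of a regulator of phosphofructokinase. Pfkl (0.51) and Pfkfb4 (0.42) followed. The 68 ribosomal protein genes were higher by a median of 0.13, with 49 above 0 and 0 called either way (adjusted p = 0.00334, and 0.38 with an estimated correlation). Rpl19 (0.41), Rps26 (0.38), Rps13 (0.37) and Rps15a (0.29) had the smallest p.

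Genes of lipid absorption and lipoproteins were lower on the HF side as a group (18 measured, 15 below 0, median -0.14; adjusted p = 0.00964, and 0.105 with an estimated correlation). None passed over all genes. The apolipoprotein genes Apoc3 (-0.89 ± 0.22, SE) and Apoa1 (-0.59 ± 0.12) passed when adjusted over the list alone, and Clps (-0.78), a pancreatic colipase, and Fabp2 (-0.56), a fatty acid binding protein of enterocytes, did not. The difference of Clps rested on the self-self array 3HG, without which it was -0.28. Over the alternatives other than the estimated correlation and fry, the adjusted p in camera ranged from 7.48e-05 to 0.37 for gluconeogenesis. It ranged from 0.000437 to 0.184 for glycolysis, 1.85e-06 to 0.184 for ribosomal proteins and 0.00501 to 0.208 for lipid absorption. For lipid absorption fry gave a lower adjusted p, 0.000306. None of the 4 lists passed without the self-self array 3HG. Neither the sugar transporters (adjusted p = 0.067, with Slc2a5 the 1 called member of 10) nor fructose and sorbitol metabolism (adjusted p = 0.0959, 7 measured) passed. None of the 10 cell type marker lists passed in camera, and the lowest adjusted p among them was 0.257, for smooth muscle. Of the 7 smooth muscle genes 5 lay below 0 and 2 above. Cnn1 (-0.71), named after its value had been seen, passed when adjusted over that list alone and not over all genes. The fry test called enteric neuron and glia genes (12 of 15 above 0; adjusted p = 0.00969), sugar transporters (0.00969), fructose and sorbitol metabolism (0.0392) and mineral and ion transport (0.00241) besides gluconeogenesis, glycolysis and lipid absorption, and did not call ribosomal proteins (0.168).

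**Figure D3:**
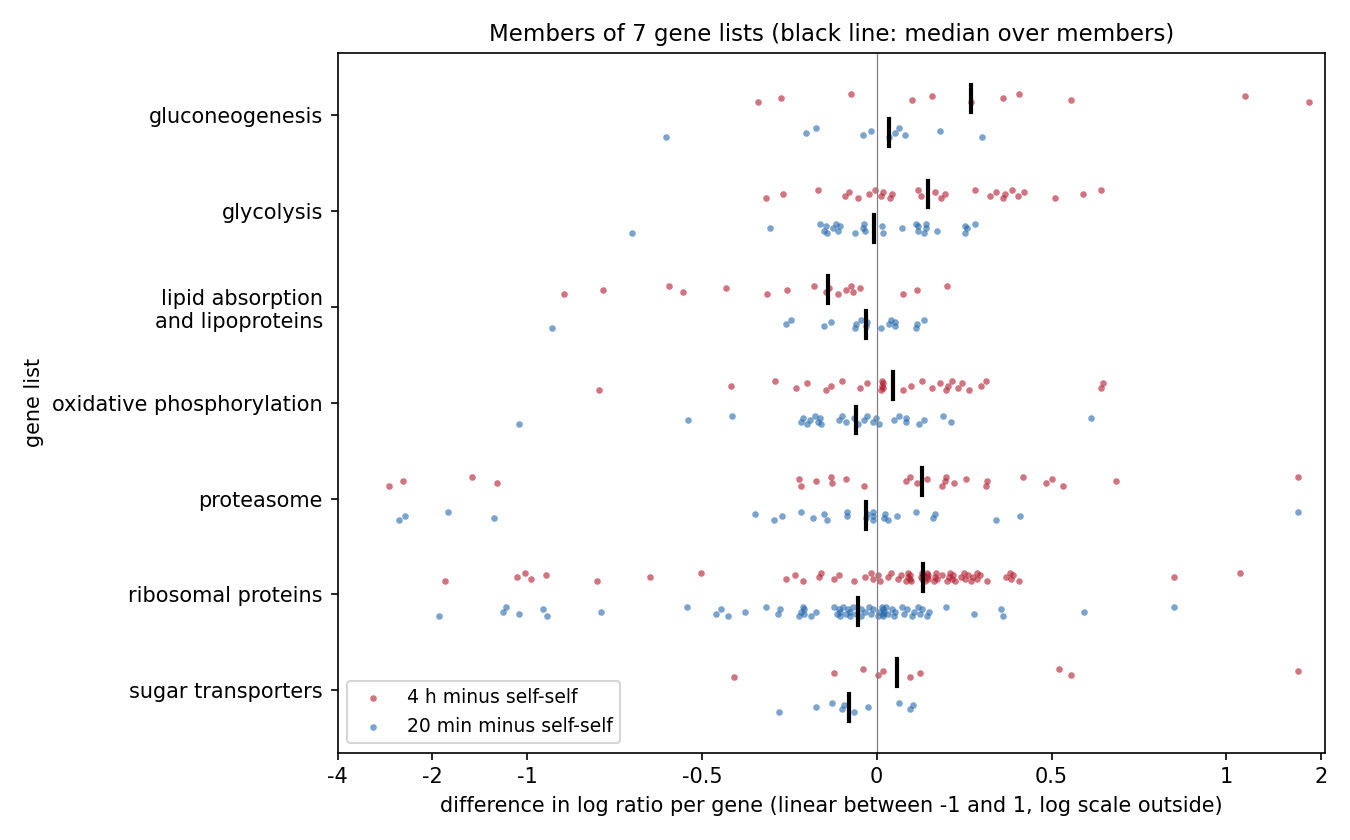
Difference in log ratio from the self-self arrays (horizontal axis, linear between -1 and 1 and logarithmic outside) for each measured gene of the 7 lists that passed at 4 h or between 4 h and 20 min (vertical axis), in red at 4 h and in blue at 20 min, with a black line at the median. The median of the 11 gluconeogenesis genes lies at 0.27 at 4 h and 0.04 at 20 min; 9 genes lie below -0.9 at both times, and all 9 had a ratio above 2 on the self-self array 1HG.

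The second comparison asked the same after 20 min. Barhl1, a homeobox gene known from the nervous system, was higher on the positive side by 1.37 ± 0.19 (SE; 2.59-fold; limma adjusted p = 0.0266; 2.68 with quantile normalization), with a mean of 1.81 ± 0.27 (SD, n = 4) at 20 min and 0.44 ± 0.30 (n = 3) on the self-self arrays. Its ratio was 0.97 on the primer array and 2.09 on array 6. Hspbp1, which encodes a partner protein of the chaperone Hsp70, was lower by -1.39 ± 0.19 (SE; adjusted p = 0.0266), with a mean of -1.45 ± 0.30 (SD, n = 4). These 2 were the features called, and 244 had an unadjusted p below 0.05. With only the 20 min and self-self arrays in the fit, or without 20 min replicate 2 or 4 or the self-self array 3HG, 0 features were called. The genes with the next smallest p were Abcb11, the bile salt export pump (0.79; adjusted p = 0.353), Crcp (-0.48; adjusted p = 0.706), and, all with an adjusted p of 0.8, Nell2 (0.74), Gdf10 (0.66), Nxph1 (0.35), Polr2f (-0.43), Plcg2 (-1.02) and Kcnv1 (-1.30).

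None of the genes fixed beforehand passed at 20 min. Slc2a5 had a difference from the self-self arrays of -0.28 ± 0.16 (SE; adjusted p = 0.8; a difference of -0.18 without the self-self array 1HG), Fbp1 of 0.30 ± 0.25 (adjusted p = 0.915; a difference of 0.14 without 20 min replicate 1 and of 0.47 without replicate 4) and Slc34a2 of 0.04 ± 0.35 (adjusted p = 0.992). G6pc1 ranged from -0.96 to 1.64 over the 4 arrays, with a difference of 0.18 ± 0.51 (adjusted p = 0.992). The differences of Slc2a2, Slc5a1, Khk and Si were -0.06, -0.10, -0.14 and -0.10, with adjusted p between 0.865 and 0.992, and that of Slc2a2 changed sign when the arrays were scaled to 1 spread. None of the 31 lists passed. The lowest adjusted p was 0.455, for the ribosomal protein genes (median -0.05), and with an estimated correlation every list had an adjusted p of 0.972.

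The third comparison asked whether the ratio of HF to HG differed between 4 h and 20 min, in which a dye effect common to both sets of arrays cancels. It assumes that the ratio has the same direction at 20 min as at 4 h, since no array at 20 min was repeated. In limma's test 28 of 4682 features differed, 13 with a higher and 15 with a lower ratio at 4 h, and 633 had an unadjusted p below 0.05. The 2 groups of arrays did not overlap in any of the 28, nor in 6.54% of all features, against 1.59% by chance. Of these, 26 have a gene symbol. Cnga3 (2.02 ± 0.11, SE; adjusted p = 2.85e-06) and Slc2a5 (1.97 ± 0.14; adjusted p = 2.89e-05) had the largest increases from 20 min to 4 h. Quantile normalization raised these to 3.23 and 3.07 and moved Barhl1, given below, to -3.16. The ratios of Slc34a2 (-1.75 ± 0.31; adjusted p = 0.0312) and Entpd2 (-1.15 ± 0.16; adjusted p = 0.0113) were lower at 4 h. G6pc1 (1.65 ± 0.45; adjusted p = 0.131) and Fbp1 (0.85 ± 0.22; adjusted p = 0.13) did not pass, nor did Slc2a2 (-0.06), Slc5a1 (0.06), Khk (0.20) and Si (0.34, and 0.12 without 4 h replicate 1), and the sign of Slc2a2 changed with the scaling of the arrays.

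Among the other named genes with a higher ratio at 4 h were Herpud1 (1.15 ± 0.21, SE; adjusted p = 0.0392), a protein of the stress response of the endoplasmic reticulum, and Prpsap1 (1.04 ± 0.16; adjusted p = 0.0154), which binds the synthetase of phosphoribosyl pyrophosphate. Pfkfb2 (0.74), Gss (0.70), which encodes glutathione synthetase, the aldehyde reductase gene Akr7a3 (0.75) and the ubiquitin ligase gene Rnf4 (0.66) passed as well. Hspbp1 (1.17) and Rimbp2 (0.82) passed with means of -1.45 and -0.78 at 20 min and of -0.28 and 0.04 at 4 h. With a lower ratio at 4 h were the cytokine gene Il15 (-0.83), Emp1 (-0.79), Cstb (-0.77), an inhibitor of cysteine proteases, S100a6 (-0.73), Add3 (-0.64), a protein of the membrane skeleton, and the corepressor Tle3 (-0.62). Tgfb2 (-0.65) was measured by 2 probes that disagreed, at -1.16 and -0.14. Barhl1 (-1.83) passed through its ratio at 20 min. Many of these calls hung on single arrays. In 10 fits with 1 array left out, Cnga3, Slc2a5, Akr7a3 and Barhl1 passed in all 10, Entpd2 in 9, Hspbp1 in 8, Prpsap1 in 7, Rnf4, Emp1 and Rimbp2 in 6 and Add3 in 5. Il15 passed in 4, Slc34a2 and Herpud1 in 3, Pfkfb2, Gss, Cstb, Tgfb2 and Tle3 in 2 and S100a6 in 1.

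In camera the ratio was higher at 4 h than at 20 min in 6 of the 31 lists and lower in 0. With an estimated correlation none of the 6 passed, with an adjusted p of 0.124 for ribosomal proteins, gluconeogenesis, oxidative phosphorylation, glycolysis and sugar transporters and of 0.229 for the proteasome. Ribosomal protein genes shifted by a median of 0.15, with 58 of 68 above 0 (adjusted p = 2.59e-07), and Rpl35 (0.63), Rpl31 (0.58), Rpl13 (0.58) and Rpl19 (0.45) had the smallest p. Gluconeogenesis genes shifted by 0.33, with 10 of 11 above 0 (adjusted p = 0.000176). Here 6 passed when adjusted over the list alone, among them G6pc1, Fbp1, Slc37a4 (0.49) and Mdh1 (0.31). Proteasome genes shifted by 0.16 (24 of 28 above 0; adjusted p = 0.000827), led by Psmb6 (0.59), Psma1 (0.50), Psmb1 (0.34) and Psmd9 (0.33, and 0.22 without 20 min replicate 3). Oxidative phosphorylation genes shifted by 0.14 (23 of 30; adjusted p = 0.00254), led by Cox5a (0.46), Cox4i1 (0.42), Cox8b (0.38) and Ndufs6-ps1 (0.26). The symbol Ndufs6-ps1 has the form used for pseudogenes, and it entered because this list was set by a pattern of symbols. Glycolysis genes shifted by 0.12 (20 of 28; adjusted p = 0.00707), with Pfkfb2 the 1 member called over all genes and Pfkl (0.62), Eno1 (0.44) and Ldhb (0.38) next. Sugar transporter genes shifted by 0.10 (6 of 10; adjusted p = 0.0325), led by Slc2a5, Slc37a4 and the insulin-responsive transporter Slc2a4 (0.65), while Slc5a3 lay at -0.32 (-0.20 without 20 min replicate 4). The median of this list was -0.01 without 20 min replicate 3 and 0.25 without 20 min replicate 4. Of the fructose and sorbitol metabolism list (adjusted p = 0.0721) 1 of 7 was called, Gpd1 (0.64; adjusted p = 0.0297), named after its value had been seen.

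Over the alternatives other than the estimated correlation and fry, the highest adjusted p in camera was 0.000877 for ribosomal proteins. It was 0.0879 for gluconeogenesis and for the proteasome, 0.16 for oxidative phosphorylation, 0.117 for glycolysis and 0.284 for sugar transporters. The lowest of each list lay between 2.03e-09 and 0.00601. The adjusted p of fry lay above the range for ribosomal proteins (0.0128) and the proteasome (0.101) and below it for sugar transporters (0.00343). The lowest adjusted p of the 10 cell type marker lists in camera was 0.291, for red blood cells, while fry called enteric neuron and glia genes (11 of 15 above 0; adjusted p = 0.0128). It also called fructose and sorbitol metabolism (0.0128), lipid absorption and lipoproteins (0.00343), vacuolar H+-ATPase subunits (0.0128) and the citric acid cycle (0.0259), and did not call the proteasome (0.101). The count of 28 fell to 4 without 20 min replicate 2 and rose to 43 without the self-self array 1HG.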

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

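The tests on the dye, the other transcript and the array set were chosen after the results had been seen, and the regrouping of arrays was planned. Of 109 gene and group combinations examined, 8 had 1 array far from the rest, and chance gives about 5%. These were Slc2a5 at 20 min replicate 2 (-0.0146, others -0.445 to -0.376), Gss at 20 min replicate 3 (-0.46, others -0.21 to -0.18) and Psmb1 at 20 min replicate 1 (-0.0576, others 0.0045 to 0.0132). At 4 h they were Gpt replicate 3 (-0.0507, others 0.37 to 0.49), Cox5a replicate 2 (0.0705, others 0.53 to 0.67), and in replicate 1 Rps15a (0.53, others 0.16 to 0.26), Rimbp2 (0.50, others -0.11 to -0.02) and S100a6 (-1.24, others -0.79 to -0.62). Replicate 1 at 4 h holds 3 of the 8.

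Of the 26 genes with a symbol that differed between 4 h and 20 min, the 10 with the largest differences in each direction are given here. With a higher ratio at 4 h they were Cnga3 (2.02), Slc2a5 (1.97), Hspbp1 (1.17), Herpud1 (1.15), Prpsap1 (1.04), Rimbp2 (0.82), Akr7a3 (0.75), Pfkfb2 (0.74), Gss (0.70) and Rnf4 (0.66). With a lower ratio they were Tle3 (-0.62), Add3 (-0.64), Tgfb2 (-0.65), S100a6 (-0.73), Cstb (-0.77), Emp1 (-0.79), Il15 (-0.83), Entpd2 (-1.15), Slc34a2 (-1.75) and Barhl1 (-1.83). The lists that differed between the times were gluconeogenesis (median 0.33), proteasome (0.16), ribosomal proteins (0.15), oxidative phosphorylation (0.14), glycolysis (0.12) and sugar transporters (0.10). None of these 6 passed with an estimated correlation (lowest adjusted p 0.124).

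Cnga3 had a ratio as large as that of Slc2a5 at 4 h although it is known from photoreceptors. A dye effect of its probe would have appeared on the other arrays, where the mean ratio of the 7 arrays at 20 min and self-self was -0.14 (range -0.31 to -0.04), which argues against it. Array 6, at -2.12, had the opposite sign. The swap of dyes on array 6 was inferred in part from that change of sign, so it is no separate evidence. Hybridisation of another transcript stays open, because Cnga3 has 1 probe and its sequence is not given in the sources used here. A second probe or a PCR assay would separate the 2 readings.

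Barhl1 and Hspbp1, the 2 genes called at 20 min, may owe their ratios to the set of arrays instead of the perfusion. For a dye effect of the array set, Barhl1 needs a high ratio on array 6, which carried 4 h RNA. The value there was 2.09, like the mean of 1.81 at 20 min and unlike 0.24 on array 2 with the same RNA pair. No label places array 6 in a set with the arrays at 20 min. On the self-self arrays, also of 4 h RNA, Barhl1 lay lower, at 0.76 (1HG), 0.40 (3HG) and 0.16 (3HF). The reading for Barhl1 thus rests on array 6 alone and is not settled. Hspbp1 on array 6 was -0.69, between its 4 h and 20 min means, and stays open. A swap of dyes at 20 min would decide both.

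The same question applies to the 28 features that differed between the times, where array set and perfusion time cannot be told apart by the design. Of 21 features further from the self-self arrays at 4 h, 80.95% (17) had array 6 beyond the 20 min mean on the opposite side, with an exact interval of 58.1 to 94.5%, and of 7 further at 20 min 57.14% (4), interval 18.4 to 90.1%. Among all features 50.77% did so, and 46.56% changed sign on array 6 against 85.71% of the 21. Both intervals treat the features as independent, which they are not, so they are likely too narrow and measure no spread between arrays. The first interval lies above the share among all features but starts below the limit set for excluding the explanation. Both shares rest on 1 array, so the explanation stays open.

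Whether arrays grouped at random give as many calls was examined by regrouping them. At 4 h 1 of 56 groupings, the real one, gave as many calls (3, highest other 2), at 20 min 1 of 35 (2, highest other 0), and between the times 1 of 100 drawn (28, highest other 4). With the repeat array left out, the real grouping thus gave more calls than any other grouping examined, by only 1 call at 4 h. This holds for that choice alone, which was made after the values had been seen. With the repeat array averaged in as deposited, all 3 comparisons had 0 calls and nothing to regroup. At 20 min the real grouping also gave 0 calls without replicate 2. Regrouping cannot tell an effect of perfusion from one of the array set, since either would favour the real grouping.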

How the results depend on the processing

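Of 2165 results for named genes under alternatives 1856 were the same, 225 weaker, 51 stronger and 33 reversed, and for lists 191 of 212 were the same and 21 weaker. The cause of these changes was not tested. For a gene not called, the same means that it stayed not called with its sign kept, and most of the named results are of that kind. Calls were therefore lost more often than the totals show. Between the times Cnga3 and Slc2a5 passed in 23 of 25 alternatives, Slc34a2 in 15 and Tle3 in 8. Filters on missing values were not run separately, since no value is missing. Counts below are genes at 4 h, at 20 min and between the times (3, 2 and 28 as reported), then lists at 4 h and between the times (4 and 6). Lists at 20 min stayed at 0 throughout. Tested against 0, genes called at 4 h numbered 763, genes called at 20 min 384 and lists at 4 h 7, and Clps at 4 h (0.0128) and Crcp at 20 min (0.0242) changed sign. That test does not take off the dye effects of probes, so its counts are not counts of genes that differ between HG and HF. With arrays scaled to 1 spread 0 genes were called at 20 min and 16 between the times, 2 and 0 on the HF and HG sides at 4 h, and Slc5a1 at 4 h (0.068) and Slc2a2 at 4 h (0.0592), at 20 min (0.0187) and between the times (0.0405) changed sign. Quantile normalization gave 2 and 0 at 4 h and 22 between the times (14 and 8), raised Cnga3 and Slc2a5 at 4 h to 3.28 and 2.74 and Barhl1 at 20 min to 2.68, and turned Slc5a1 at 4 h (0.0816) and Slc2a2 at 4 h (0.037) and between the times (0.132). Array 6 averaged as deposited gave 0, 0 and 0 genes, with Slc5a1 at 4 h 0.0096 and Slc2a2 between the times 0.0244. Averaged turned it gave 0 at 20 min and 18 between the times, with Slc5a1 0.0124 and Slc2a2 0.0287. In place of array 2 as deposited it gave 0, 0 and 0 genes and 0 and 2 lists, with Slc5a1 at 4 h 0.0589, Slc2a2 at 4 h 0.0398 and between the times 0.105. In place and turned it gave 0 at 20 min and 4 between the times, with Slc5a1 0.0644, Slc2a2 at 4 h 0.0485 and between the times 0.113. Turned and averaged with a dye term it gave 17, 0 and 21. Cnga3 and Slc2a5 at 4 h passed in 21 of 23 alternatives (adjusted p 5.85e-08 to 0.762 and 1.07e-06 to 0.762), Entpd2 at 4 h in 10 of 23 (5.76e-05 to 0.759), and Barhl1 and Hspbp1 at 20 min in 10 and 11 of 22 (1.26e-05 and 6.03e-05 to 1). Only 2 groups in the fit gave 0 at 20 min and 37 between the times, no centring 25, robust empirical Bayes 31 and array weights (0.42 for 1HG to 1.51 for 3HF) 35. Adjusted p under 0.1 gave 55 genes between the times and 9 and 10 lists. Estimated correlation gave 0 and 0 lists, and fry 7 and 10. Values of 1HG beyond 2 set to missing gave 46 genes between the times. Without 4 h replicates 1, 2 and 3 the genes between the times numbered 9, 15 and 13, and without 20 min replicates 1 to 4 12, 4, 9 and 7, and 43 without 1HG. Genes at 4 h numbered 2 to 5 (5 without 4 h replicate 2). At 20 min they numbered 1, 0, 1 and 0 without replicates 1 to 4, 0 without 3HG and 4 without 3HF. Lists numbered 7 without 1HG and 0 without 3HG at 4 h, and 6 to 10 between the times (10 without 4 h replicate 5). With 1 replicate left out signs also turned in genes not called. Slc5a1 ranged at 4 h from -0.147 (without 3HG) to 0.0265 (without 1HG), at 20 min from -0.339 to 0.131 (without replicates 4 and 1) and between the times from -0.17 to 0.299. Slc2a2 ranged from -0.15 to 0.0566 at 20 min and -0.177 to 0.0296 between the times, G6pc1 from -0.288 to 0.577, Si from -0.23 to 0.0339 and Slc34a2 from -0.0381 to 0.193, all at 20 min. The replicate number as a block gave 22 genes (13 shared) and 9 lists, and arrays of equal number did not pair (correlations of -0.07, 0.16, -0.03 and -0.02).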

Other observations

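Lists that did not pass as a whole held single genes with large ratios, picked out after their values had been seen, and none of those in this paragraph except Herpud1 passed over all genes. Between 4 h and 20 min the water channel gene Aqp8 differed by 1.40 (limma adjusted p = 0.0581; 0.00707 adjusted over the list of mineral and ion transport alone). In the same list Scnn1a, a subunit of the epithelial sodium channel, had a difference of 0.38 (adjusted p = 0.13; 0.0302 over the list alone). The folate carrier gene Slc19a1 differed by 1.13 (adjusted p = 0.057) and Slc3a2, the heavy chain of amino acid exchangers, by 0.56 (adjusted p = 0.122; 0.0207 over the list alone). In the heat shock and ER stress list Trib3 differed by 0.65 (adjusted p = 0.0542; 0.00403 over the list alone), next to Herpud1.

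Of the immediate early genes Zfp36 differed by 0.61 and the feedback regulators Dusp6 and Klf10 by -0.85 and -0.74 between 4 h and 20 min, with adjusted p over all genes of 0.0801, 0.13 and 0.13 and over the list alone of 0.021, 0.0229 and 0.0229. The list as a whole had a median of -0.08 in this comparison (adjusted p = 0.294) and of -0.12 at 4 h (adjusted p = 0.45). In the citric acid cycle list Idh1 (0.37), Mdh1 (0.31) and Idh3g (0.21) passed over the list alone, and the list had an adjusted p of 0.0595. For Apoc3 and Apoa1 the difference between the times was -0.91 and -0.44, not past the threshold (adjusted p = 0.0801 and 0.126).

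On the primer array 5 probes lay beyond 1 in either direction. The named genes among them were Or8g20b (1.51), Tgfb3 (-1.32), Cd9 (1.25) and Cpb1 (-1.03).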
